A study of Homo sapiens with 4 samples.

How the data were processed

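The series holds 4 single-cell RNA libraries of human bone marrow mononuclear cells (BMMC), 2 titled ET and 2 titled H. Per the labels, cells carrying the surface proteins CD34 (progenitors) and CD14 (monocytes) were picked with magnetic beads, counted and pooled by hand before loading on a 10x Genomics Chromium instrument (3′ v3.1 chemistry). The titles gave the groups and replicate numbers (ET replicates 1 and 3, H replicates 1 and 2). The labels do not spell out ET or H. The labels do not say whether each library of a group came from a different individual, so p-values here measure the spread between these libraries, which may in part be technical.

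The deposited files hold raw UMI counts, whole numbers of unique molecules per gene and cell barcode, with 36601 genes in each library. Reads were processed with Cell Ranger 6.1.1 against GRCh38, per the submitters' processing notes. The gene annotation and the strand setting of that counting are not given in the sources used here. Every barcode in the deposited files held at least 500 UMI counts. Gene names came from the files. Positions came from GENCODE release 29 on GRCh38, in which 34616 of the 36601 gene IDs were found (94.6%). That release may not be the annotation the authors used.

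Cells with at least 500 genes detected and at most 20% mitochondrial counts were kept. Doublets were called per library with scrublet in scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes up to 10%, and 624 of the 24389 cells that passed the filters were removed. The remaining 23765 cells were scaled to 10000 UMIs each and log-transformed. The 2000 most variable genes, chosen within each library, gave 30 principal components, from which 20 neighbours per cell and Leiden clustering at resolution 1 gave 24 clusters. Mitochondrial and ribosomal genes and the variable, diversity and joining segments of immunoglobulin and T-cell receptor genes were kept out of the clustering. Constant-region genes such as IGKC were not. A set of 105 genes that could point to a person, such as those on the Y chromosome, was left out of each step and is not reported here. No step aligned the libraries to one another.

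A cluster was called "X-like" from marker lists fixed before the data were examined. The thresholds of the naming were set after the clusters had been seen. They asked for a mean marker score of at least 0.25 (log2), a next-best class at no more than 0.75 of that score, and at least 3 markers. A marker counted when it was detected in 10% of the cells and stood 0.25 (log2) above the mean. No more markers of another class than of the own class could be among the 10 leading genes. Clusters 8, 10 and 16 stayed unnamed, and their share is given per library. Class shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. No test of shares was run, a choice made before the data were examined, because CD34+ and CD14+ cells were pooled by hand. An exact permutation test of 2 against 2 libraries cannot go below a p of 0.333, and a parametric test was not tried.

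Libraries were the replicates. Raw counts were summed per library and class, for classes with at least 20 cells in each library. The ET and H sums were compared by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with TMM scaling. Genes were kept by filterByExpr (minimum count 10, minimum total 15). Adjusted p-values are Benjamini-Hochberg values over all genes tested, and 0.05 was the threshold. CPM values of tested classes are edgeR CPM of such sums, scaled with the TMM factors; those of classes with too few cells are counts over the class total. Standard errors of log2 fold changes were derived from the F statistic. The difference of the ET effect between classical monocyte-like and HSPC-like cells (hematopoietic stem and progenitor cells) was an interaction term in 1 model over both classes, with the library as a block. Gene lists were tested by limma's camera (limma 3.58.1) with its preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry stood beside it. Of the 32 lists, those with at least 3 members tested were used in each class.

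Named genes followed a rule fixed before the data were examined: LGALS1 in each class; in the main comparisons the genes past the threshold with the largest changes, a mean of at least 20 CPM and no overlap of the groups; otherwise the 10 smallest p-values; 3 genes each way in other classes; and the members of each list with the smallest p. Genes with donor-specific haplotypes, clone-based names and LINC names were left out by that rule. The list members named in the text were limited, after results had been seen, to the lists that camera called, the galectins and a few others. LAMB3, LINC02432, BCL2A1, IL1A, CXCL8, TNIP1, IL6, EGR3, CSRNP1, DUSP2, ROBO1, SPATC1L, ALOX5, ALOX5AP, CA1, TNNI3, SYT5 and, for the difference between the classes, SLC16A10 were named after their values had been seen.

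The analysis was tested on counts simulated from the real means and library sizes, with 200 genes changed. In the monocyte simulation over 14797 genes, edgeR called 1 of 200 genes changed 2-fold, 132 changed 4-fold and 195 changed 16-fold. False calls beside them were 5, 14 and 20. In the HSPC simulation over 20602 genes it called 0, 107 and 184, with 0, 13 and 25 false calls. For the difference between the classes, over 19707 genes, it called 12, 90 and 165, with 20, 7 and 28 false calls. At 2-fold, false calls thus outnumbered true calls in the monocyte and difference simulations. In the granulocyte-monocyte progenitor simulation, the 2-fold setting gave 62 true and 30 false calls. DESeq2 1.42.0 called 134 of the 4-fold genes in the HSPC simulation, with 63 false calls against 13 by edgeR. For lists, the 38 type I interferon response genes were shifted 2-fold. Camera with the preset correlation called them (adjusted p = 7.07e-37 in the monocyte and 3.9e-32 in the HSPC simulation) and called 0 of the 29 lists that hold none of these genes. With an estimated correlation it missed them in both (0.133 and 0.153). Fry called them in the monocyte simulation (0.0450) and missed them in the HSPC simulation (0.0849). The simulated genes were drawn independently, so none of these settings was tested on genes that vary together. Among the lists that camera called in the real data, the estimated correlation ranged from -0.079 to 0.991.

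The alternatives were other size factors (RLE), no filter on low counts, doublets kept, a stricter cell filter (1000 genes and 10% mitochondrial counts), Leiden resolution 2, clustering of each library alone, equal numbers of cells per library, each library left out in turn, DESeq2, an estimated correlation between genes, and wider classes. Alternatives added after the data had been seen left out clusters with a median mitochondrial share above 10%, added the unnamed HSPC-matching cluster, or used the HSPC cluster that each library fills with 20 or more cells. After results had been seen, the level of selected genes that monocyte RNA would bring to HSPC-like droplets was computed from the ratio of S100A9 in HSPC-like to monocyte-like cells of the same library. The computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.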

Results

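The transcriptomes of CD34+ and CD14+ bone marrow cells were measured in 2 ET and 2 H libraries. The series title names galectin-1, the protein made from LGALS1, and inflammation driven by monocytes in myeloproliferative neoplasms. The files held 9231 barcodes for ET replicate 1, 4915 for ET replicate 3, 5205 for H replicate 1 and 11382 for H replicate 2. Total UMI counts in the same order were 89382720, 114129507, 101797983 and 156508946. After filtering and removal of doublets, 7171, 3855, 4091 and 8648 cells remained. Their median UMI counts were 9886, 25390, 19222 and 14138, and their median numbers of genes were 3453, 5865, 5077 and 4391. ET replicate 1 was the shallowest library per cell.

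The cells fell into HSPC-like, classical monocyte-like, erythroid-like, granulocyte-monocyte progenitor-like, megakaryocyte-like, B-lineage-like, basophil, mast cell or eosinophil progenitor-like, plasmacytoid dendritic cell-like and T or NK cell-like classes. HSPC-like cells made up 75.8% of ET replicate 1 (95% interval 74.8 to 76.8%), 26.4% of ET replicate 3, 24.3% of H replicate 1 and 36.2% of H replicate 2. Classical monocyte-like cells made up 11.6%, 17.7%, 23.1% and 14.6% in the same order. B-lineage-like cells made up 2.55% and 2.08% of the ET libraries and 7.90% and 6.53% of the H libraries. Plasmacytoid dendritic cell-like cells made up 0.390% and 0.337% in ET and 2.08% and 1.503% in H. Erythroid-like cells ranged from 3.03% in ET replicate 1 to 21.0% in ET replicate 3, with 12.8% and 10.2% in H. Megakaryocyte-like cells made up 0.641% and 6.74% in ET and 4.64% and 2.38% in H. Granulocyte-monocyte progenitor-like cells made up 2.05% and 8.77% in ET and 6.60% and 5.27% in H. Basophil, mast cell or eosinophil progenitor-like cells made up 0.460% and 3.48% in ET and 1.52% and 0.867% in H. T or NK cell-like cells made up 0.488% and 0.415% in ET and 1.30% and 0.636% in H. Unnamed clusters held 3.03%, 13.1%, 15.8% and 21.8% of the cells of ET replicates 1 and 3 and H replicates 1 and 2. The pooling of CD34+ and CD14+ cells by hand can set these shares, and they were not tested. The high HSPC-like share of ET replicate 1 was also seen without monocyte-like cells in the total. Of HSPC-like, erythroid-like, megakaryocyte-like and the 2 other myeloid progenitor-like classes together, HSPC-like cells made up 92.5% in ET replicate 1. They made up 39.8% in ET replicate 3, 48.7% in H replicate 1 and 66.0% in H replicate 2. The ET minus H difference of the B-lineage-like share, -4.90 percentage points, was -2.61 with doublets kept, -2.21 with the stricter cell filter and -2.59 at Leiden resolution 2. That of plasmacytoid dendritic cell-like cells, -1.43, was -3.03 with doublets kept. With each library clustered alone, the granulocyte-monocyte progenitor-like difference went from -0.53 to 3.15 and that of T or NK cell-like cells from -0.51 to -0.97. The granulocyte-monocyte progenitor-like difference was also 1.49 at Leiden resolution 2, 0.03 with the stricter cell filter and -0.05 with doublets kept. That of megakaryocyte-like cells, 0.18, was -0.51 with the stricter cell filter and -0.20 with each library clustered alone. With the stricter cell filter, HSPC-like cells went from 20.8 to 12.2, erythroid-like cells from 0.55 to -0.36 and unnamed cells from -10.75 to -3.29.

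**Figure D1:**
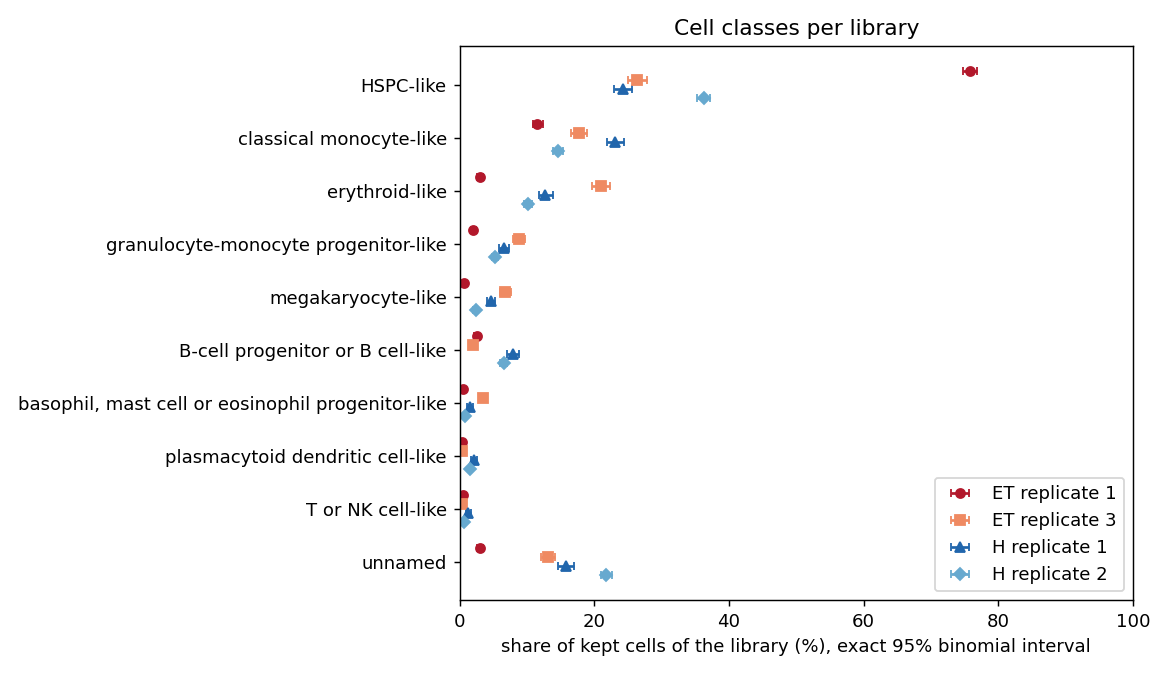
Share of kept cells in each class (x axis, percent of the library's cells) for the 4 libraries, with exact 95% binomial intervals. The HSPC-like share of ET replicate 1, 75.8%, stands apart from 24.3 to 36.2% in the others.

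LGALS1 RNA was higher in classical monocyte-like than in HSPC-like cells in each of the 4 libraries. It stood 3.94 (log2, SE 0.33) higher within the same library (edgeR adjusted p = 1.26e-05). Classical monocyte-like cells held 408 and 912 CPM in ET replicates 1 and 3 and 390.2 and 528 CPM in H replicates 1 and 2. HSPC-like cells held 14.9 and 65.0 CPM in ET and 67.7 and 52.6 CPM in H. Plasmacytoid dendritic cell-like cells, too few to test, held 543 and 914 CPM in ET and 654 and 584 CPM in H. T or NK cell-like cells, also not tested, held 83.9 and 19.1 CPM in ET and 49.0 and 51.5 CPM in H. The values of these untested classes are counts over the class total, without TMM factors. LGALS1 (ENSG00000100097) lies on the plus strand of chromosome 22 of GRCh38, from 37675608 to 37679806.

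LGALS1 RNA was compared between ET and H in each tested class, while the series title names the protein. In classical monocyte-like cells the difference did not exceed the spread between libraries. A change of this size would rarely be called: edgeR called 1 of 200 genes changed 2-fold in the monocyte simulation and 0 in the HSPC simulation. In classical monocyte-like cells the log2 fold change of ET against H was 0.52 (SE 0.43, edgeR adjusted p = 0.777). It was 0.97 without ET replicate 1, -0.17 without ET replicate 3 and 0.32 without H replicate 1, so its sign rested on ET replicate 3. In HSPC-like cells the log2 fold change was -0.59 (SE 0.69, adjusted p = 0.989). It was 0.12 without ET replicate 1, -0.40 without H replicate 1 and -2.02 without ET replicate 3, where it passed the threshold (adjusted p = 0.0174, range over the alternatives 0.0174 to 1.000). In megakaryocyte-like cells LGALS1 held 31.7 and 79.4 CPM in ET and 18.9 and 11.2 CPM in H, a log2 fold change of 1.97 (SE 0.46) with an unadjusted p of 0.00645 and an adjusted p of 0.376. That value was 1.06 without ET replicate 3. It passed the threshold without ET replicate 1 (2.39, adjusted p = 0.0182, range over the alternatives 1.06e-09 to 0.999). In granulocyte-monocyte progenitor-like cells LGALS1 held 185 and 299 CPM in ET and 217 and 265 CPM in H. Its log2 fold changes there and in the basophil, mast cell or eosinophil progenitor-like, erythroid-like and B-lineage-like classes were 0.01, 0.04, -0.41 and -0.17. None of them passed (adjusted p = 0.806 to 0.999). The signs of the first pair rested on single libraries: without ET replicate 3 they were -0.39 and -0.72, and without H replicate 1 they were -0.12 and -0.07. Over the alternatives these 4 values ranged from -0.39 to 0.51, -0.72 to 0.52, -1.26 to -0.14 and -4.14 to 0.23; the -4.14 came with each library clustered alone and the -1.26 with equal numbers of cells.

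**Figure D2:**
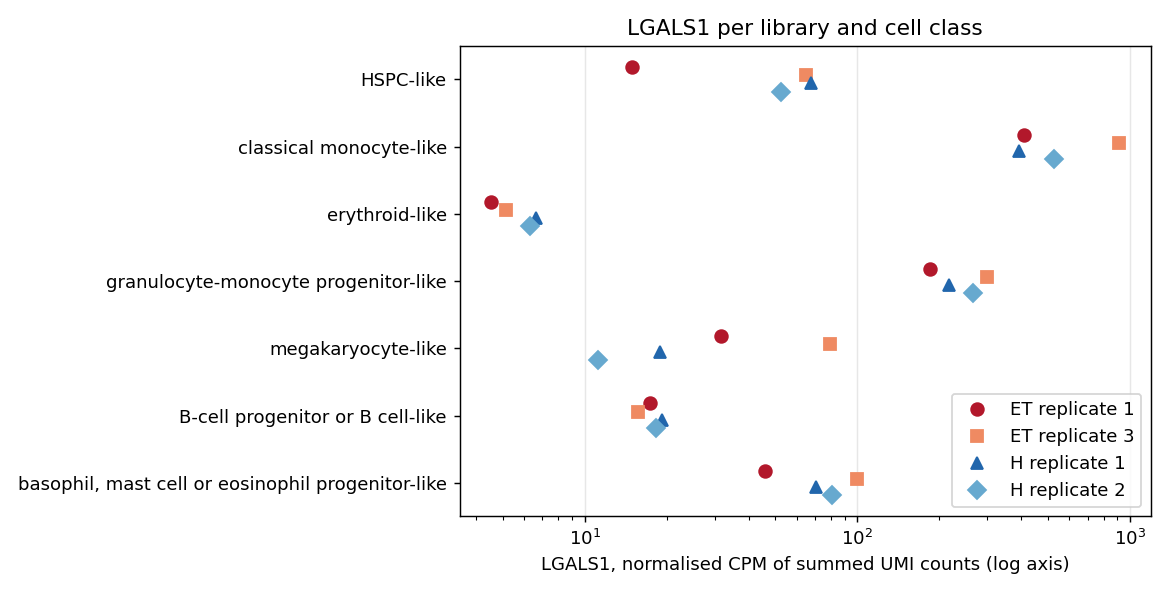
LGALS1 per library and cell class, as normalised CPM of the summed UMI counts (x axis, log scale). Each point is 1 library; classical monocyte-like cells hold 390.2 to 912 CPM and HSPC-like cells 14.9 to 67.7 CPM.

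Classical monocyte-like cells of the ET libraries held more OLR1, APBB2 and LAMB3 RNA than those of the H libraries, and less LINC02432. OLR1, which encodes the oxidised-LDL receptor LOX-1, rose by 5.65 on the log2 scale (SE 0.42, edgeR adjusted p = 0.0283), with 42.0 and 75.7 CPM in ET and 1.10 and 1.21 CPM in H. APBB2, which encodes an adaptor that binds the amyloid precursor protein, rose by 4.81 (SE 0.31, adjusted p = 0.0283), with 48.3 and 66.2 CPM in ET and 2.03 and 2.02 CPM in H. LAMB3, which encodes a laminin chain, rose by 4.92 (SE 0.37, adjusted p = 0.0283), with 20.9 and 30.01 CPM in ET and 0.845 and 0.810 CPM in H. The non-coding RNA LINC02432 fell by 3.05 (SE 0.25, adjusted p = 0.0367), with 9.98 and 11.6 CPM in ET and 85.9 and 93.6 CPM in H. OLR1 (ENSG00000173391) lies on the minus strand of chromosome 12 of GRCh38, from 10158301 to 10172138. APBB2 (ENSG00000163697) lies on the minus strand of chromosome 4, from 40810027 to 41216714. LAMB3 (ENSG00000196878) lies on the minus strand of chromosome 1, from 209614870 to 209652466. These 4 were the genes past the threshold among 14797 tested by edgeR. In all, 1287 genes had an unadjusted p under 0.05, and DESeq2 called 158 (137 higher and 21 lower), among them all 4. The class was made up of different clusters in the groups: cluster 0 held 83.2% and 69.0% of it in H, against 23.0% and 5.70% in ET. Cluster 6, with CXCL8 and PLAUR among its leading genes, held 47.2% and 82.0% in ET, against 3.17% and 12.6% in H. Cluster 9 held the rest. With ET replicate 1, ET replicate 3, H replicate 1 or H replicate 2 left out, edgeR called 80, 2, 37 and 20 genes; without ET replicate 3, LAMB3 (4.64) and LINC02432 (-3.17) no longer passed, both at an adjusted p of 0.0686. With doublets kept, a stricter cell filter, or each library clustered alone, APBB2 stood at 3.83, 3.86 and 3.83 and did not pass (adjusted p = 0.135, 0.194 and 0.262, range over its alternatives 7.75e-27 to 0.262). With each library clustered alone, LINC02432 did not pass either (-2.89, adjusted p = 0.0900). Over their alternatives, adjusted p ranged from 6.36e-16 to 0.0900 for LINC02432 and from 1.75e-16 to 0.0686 for LAMB3.

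Genes of the NF-kB and TNF response, the transcripts that inflammatory signals induce in monocytes, stood higher as a list in ET monocyte-like cells. Of 34 members tested, 33 had a positive log2 fold change, with a median of 1.33 (camera adjusted p = 1.5e-19, or 0.698 with an estimated correlation). Fry, which called the simulated shift in monocyte-like cells, called none of the lists here. Its adjusted p was 0.737 for this list and 0.537 or above for each list. Camera with an estimated correlation also missed a simulated 2-fold shift of 38 genes (adjusted p = 0.133), but those genes were drawn independently. The estimated correlation among the members of this list was 0.90, far above the preset value behind the p of 1.5e-19. The simulation therefore gives no ground to set aside the call lost here. No member passed over all genes, while 8 rose when adjusted over the list alone: PTGS2, G0S2, PLAUR, BCL2A1, IL1A, CXCL8, TNIP1 and IL6. PTGS2, which encodes the prostaglandin-forming enzyme COX-2, held 177 and 206 CPM in ET and 33.6 and 28.9 CPM in H (2.62, SE 0.24; adjusted p = 0.0663 over all genes, 0.000762 over the list alone). G0S2, which encodes an inhibitor of fat breakdown, held 343 and 846 CPM in ET and 20.2 and 6.80 CPM in H (5.46, SE 0.73). CXCL8, the neutrophil-attracting chemokine interleukin-8, held 706 and 2197 CPM in ET and 360.2 and 278 CPM in H (2.19, SE 0.55). PLAUR, the urokinase receptor, held 1096 and 1294 CPM in ET and 444 and 294 CPM in H (1.69, SE 0.33). The list's level, a median of member values centred over the 4 libraries (log2), was -0.21 in ET replicate 1, 1.35 in ET replicate 3, -0.28 in H replicate 1 and -0.90 in H replicate 2. Without ET replicate 3 the median fold change was 0.12, against 1.81 without ET replicate 1. Without ET replicate 3, CXCL8 was 1.14, IL1A 1.71 and TNIP1 0.70; without ET replicate 1, CXCL8 was 2.76 and passed over all genes. The adjusted p of the list ranged from 7.06e-50 to 0.698 over the alternatives.

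**Figure D3:**
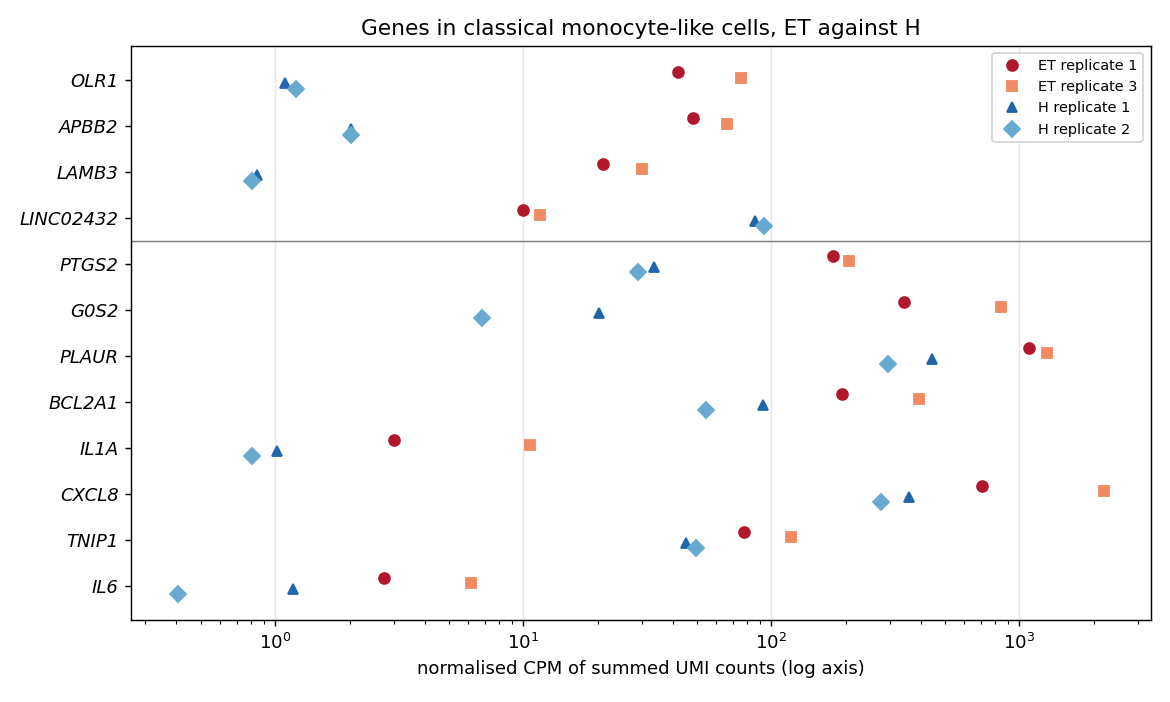
Normalised CPM (x axis, log scale) in classical monocyte-like cells of the 4 libraries, 1 point each. The upper 4 genes passed over all genes tested; the lower 8 passed when adjusted over the NF-kB and TNF response list alone, with both ET points above both H points.

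Camera also called immediate early genes and targets of JAK-STAT signalling higher in these cells, where 13 of 22 and 10 of 17 had a positive log2 fold change. The level of the immediate early list was highest in an H library: -0.30 in ET replicate 1, 0.23 in ET replicate 3, 0.27 in H replicate 1 and -0.49 in H replicate 2. Among 22 immediate early genes, 6 rose when adjusted over the list alone and none passed over all genes: the nuclear receptors NR4A3 (2.44) and NR4A1 (1.92), the zinc finger factors EGR2 (1.38) and EGR3 (2.69), CSRNP1 (1.19) and the phosphatase DUSP2 (2.20; 1.43 without ET replicate 3). The list median was 0.23 (camera adjusted p = 0.0261; adjusted p = 0.813 with an estimated correlation). It was -0.19 without ET replicate 3 and -0.11 without H replicate 2, with no call in either case, and 0.60 without H replicate 1. Among 17 JAK-STAT targets, the cytokine OSM (1.96, SE 0.28; 26.1 and 33.5 CPM in ET, 8.45 and 6.80 CPM in H) and BCL3 (1.44) rose when adjusted over the list alone, and none passed over all genes. The list median was 0.28 (camera adjusted p = 0.0461; adjusted p = 0.698 with an estimated correlation). The call ended without ET replicate 1 (0.10), without ET replicate 3 (0.26) and without H replicate 2 (0.15), and the median was 0.56 without H replicate 1. Without the filter on low counts neither list was called, with medians of 0.17 and 0.23. Adjusted p ranged over the alternatives from 1.4e-07 to 0.813 for the immediate early genes and from 0.000201 to 0.698 for the JAK-STAT targets.

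Heat shock genes and the genes of MHC class II antigen presentation stood lower as lists in ET monocyte-like cells. Of 13 heat shock genes 11 had a negative log2 fold change, with a median of -0.41 (camera adjusted p = 0.000183; adjusted p = 0.698 with an estimated correlation). HSPH1 fell by 1.55 when adjusted over the list alone (SE 0.24) and did not pass over all genes. HSPA6 and HSPA1B stood at -1.27 and -1.60 and did not pass. The heat shock median was -0.62 without H replicate 1 and -0.24 without H replicate 2. Of 11 MHC class II genes 10 had a negative log2 fold change, with a median of -0.66 (camera adjusted p = 0.000673; adjusted p = 0.698 with an estimated correlation). No member passed over all genes, nor when adjusted over the list alone. CIITA, the transcriptional activator of these genes, stood at -1.09, HLA-DPA1 at -0.72 and HLA-DQA1, whose alleles differ in sequence between people, at -1.86. Without H replicate 1 these were -0.50, -0.12 and -0.83; CIITA was also -1.66 without ET replicate 1 and -0.70 without ET replicate 3, and HLA-DPA1 -1.15 without H replicate 2. The MHC class II median was -0.06 without H replicate 1 and -0.48 without ET replicate 1, with no call in either case, and -1.11 without H replicate 2. Over the alternatives, adjusted p ranged from 3.85e-05 to 0.698 for heat shock and from 7.63e-12 to 0.698 for MHC class II.

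Among the lists for other cell types, camera called the megakaryocyte and platelet list and the stem cell program higher in ET monocyte-like cells. The megakaryocyte and platelet list had a median of 0.99 over 17 genes, 13 of them positive (camera adjusted p = 0.000448; adjusted p = 0.698 with an estimated correlation), with GP6 at 1.57, CLU at 2.38 and GP1BB at 2.35, none of them past the threshold over all genes or over the list alone. That median was 0.34 without ET replicate 3, where GP1BB was 1.31; CLU was 1.36 without ET replicate 1. The stem cell program list had a median of 0.92 over 14 genes, 12 of them positive (camera adjusted p = 0.00094; adjusted p = 0.698 with an estimated correlation), with HLF at 3.19, CRHBP at 1.46 and MECOM at 1.69, none of them past either threshold. Without ET replicate 1 these 3 were 1.13, 0.64 and 0.47. Over the alternatives HLF went down to 0.51, CRHBP to 0.03 and GP1BB to 0.96. Its level was 1.09 in ET replicate 1, the library with 75.8% HSPC-like cells, against -0.20 in ET replicate 3, -1.08 in H replicate 1 and 0.06 in H replicate 2. Its median was 0.17 without ET replicate 1 and 0.47 without H replicate 1, with no call in either case, and 1.66 without H replicate 2. The call also ended with doublets kept (0.19), a stricter cell filter (0.58), Leiden resolution 2 (0.35) and each library clustered alone (-0.08). Adjusted p ranged over the alternatives from 7.03e-05 to 0.698 for the megakaryocyte and platelet list and from 6.77e-11 to 0.728 for the stem cell program.

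Camera called none of the other lists in monocyte-like cells. The galectins had a median of 0.15 over 7 genes (adjusted p = 0.116), with LGALS2 at 1.42 (SE 0.29; 70.6 and 111 CPM in ET, 32.9 and 34.9 CPM in H), which rose when adjusted over the list alone (adjusted p = 0.0144) and did not pass over all genes. LGALS12 stood at 0.80 (0.43 without H replicate 1 and 1.30 without H replicate 2). The galectin median was 0.32 without H replicate 1 and 0.36 without H replicate 2. Clustering each library alone brought the galectin list past the threshold (0.18, adjusted p = 0.0281, range over the alternatives 0.0281 to 0.698). In the list of TGF-beta and matrix factors (median 0.35, adjusted p = 0.0805), SMAD3 (1.71) and THBS1 (3.77) rose and TGFBI fell by 1.14 when adjusted over the list alone, with none past the threshold over all genes. THBS1 rested on ET replicate 3, at 1.90 without it. NLRP3, the sensor of an inflammasome, stood at 1.52 (0.91 without ET replicate 3) and did not pass, while the inflammasome list had a median of -0.11. CLEC10A in the dendritic cell list (median -0.51) fell by 1.38 and KLRD1 in the T and NK cell list (median 0.10) rose by 2.40 when adjusted over their lists alone, neither past the threshold over all genes. Galectin-1 binding partners had a median of 0.09, S100 proteins 0.41, type I interferon response genes 0.00, interferon-gamma response genes -0.07 and Toll-like receptor sensing genes 0.23. Monocyte migration and adhesion genes had a median of 0.18, scavenger receptors and complement -0.27, oxidative burst and antioxidants 0.11 and glycolysis 0.22. Nuclear oxidative phosphorylation genes had a median of -0.13, mitochondrially encoded transcripts 0.21, ribosomal proteins -0.07 and the unfolded protein and integrated stress response -0.09. The S phase list had a median of -0.28, the G2/M list -0.11, the erythroid list -0.22, azurophil granule genes 0.36, neutrophil granule genes 0.30 and the B and plasma cell list -0.66. Camera's direction for the unfolded protein list followed its median, while its mean was 0.04.

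In HSPC-like cells, camera called the NF-kB and TNF response, S100 and platelet lists higher in ET and the cell cycle and lymphoid lists lower, with no single gene past the threshold. With an estimated correlation 0 lists were called. A simulated 2-fold shift of 38 genes was missed there too (camera adjusted p = 0.153), but those genes were drawn independently. Among the lists called here, the estimated correlation ranged from -0.08 (B and plasma cell list) to 0.99 (S phase list). The platelet and G2/M medians were 0.19 and 0.02 without ET replicate 1. By edgeR 0 of 20602 genes passed, 1031 had an unadjusted p under 0.05, and DESeq2 called 186 (74 higher and 112 lower). Without ET replicate 1, ET replicate 3, H replicate 1 or H replicate 2, edgeR called 146, 801, 1 and 0 genes. The 10 smallest p-values, none passing (adjusted p = 0.454 to 0.462), included APBB2 at 2.19 (38.8 and 34.9 CPM in ET, 8.95 and 7.24 CPM in H) and the neurexin gene NRXN3 at 3.17. They also included TNNT1, which encodes a skeletal troponin, at 5.59, DNAAF3 at 4.06, TRHDE at 3.65 and GRASP at 3.05. Lower in ET were CSGALNACT1 at -2.82, FAT3 at -3.79, OVCH1-AS1 at -5.32 and FER1L6-AS1 at -7.04; the last pair are antisense genes. Over the alternatives FAT3 ranged from -4.73 to -2.06, CSGALNACT1 from -3.06 to -1.88, DNAAF3 from 3.75 to 6.28 and NRXN3 from -1.07 to 3.84. APBB2 passed without ET replicate 1 (2.12, adjusted p = 0.0207) and without ET replicate 3 (2.26, adjusted p = 0.012), with a range over the alternatives of 6.68e-11 to 0.834. The class was made up of different clusters in each library. Cluster 1 held 71.3% of it in ET replicate 1 and cluster 5 another 21.9%, while cluster 15 held 86.7% in ET replicate 3. In H replicates 1 and 2, cluster 2 held 47.3% and 35.7% and cluster 12 held 28.7% and 39.9%.

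The NF-kB and TNF response stood higher in ET HSPC-like cells too, with a median of 0.46 over 31 genes, 23 of them positive (camera adjusted p = 3.99e-06; adjusted p = 0.719 with an estimated correlation). G0S2 stood at 4.34 and passed when adjusted over the list alone, not over all genes. With S100A9 as the tracer, RNA from monocytes in HSPC-like droplets would bring 65.0% and 84.0% of the G0S2 level in ET replicates 1 and 3, so this value is not read as a change in HSPC-like cells. For EREG that share was 0.735% and 0.768%, and for CXCL8 10.5% and 47.1%. CXCL8 was 1.25 without ET replicate 1 and 3.19 without ET replicate 3, where it passed over all genes. EREG, an epidermal growth factor family ligand, stood at 1.10 (237 and 350.1 CPM in ET, 134 and 139 CPM in H) and CXCL8 at 2.54. The S100 proteins had a median of 0.61 over 7 genes, 6 of them positive (camera adjusted p = 0.00455; adjusted p = 0.782 with an estimated correlation), with S100A8 at 1.11 and S100A9 at 0.97, none past either threshold. Monocyte RNA would bring 102.5% and 82.4% of the S100A8 level in ET and 119% and 101% in H, so S100A8 and S100A9 here can be that background. They were 0.62 and 0.49 without ET replicate 1, 0.56 and 0.48 without H replicate 1, and 2.04 and 1.73 without H replicate 2. The S100 call ended without ET replicate 1 (0.45), without ET replicate 3 (0.86) and without H replicate 1 (0.48). The megakaryocyte and platelet list had a median of 0.60 over 20 genes, 16 of them positive (camera adjusted p = 0.000147; adjusted p = 0.854 with an estimated correlation), where GP1BB rose by 1.27 when adjusted over the list alone and SELP stood at 2.56 (0.88 without ET replicate 1, and 3.32 without ET replicate 3, where it passed over all genes). Without ET replicate 1 that median was 0.19 and the call ended; without ET replicate 3 it was 0.91. The erythroid list had a median of 0.19 over 18 genes, 16 of them positive (camera adjusted p = 0.0278; adjusted p = 0.854 with an estimated correlation), with HBD at 1.14 (0.65 without ET replicate 3). The erythroid median was 0.62 without ET replicate 1 and 0.75 without H replicate 2, and the call ended without ET replicate 3 (0.30) and without H replicate 1 (0.19). The S100 and erythroid calls also ended with doublets kept, the stricter cell filter, Leiden resolution 2, each library clustered alone and the unnamed HSPC-matching cluster added, and the platelet call with the last of these. The erythroid call ended without the filter on low counts as well. Over the alternatives GP1BB ranged from -0.01 to 1.42 and HBD from -0.19 to 1.99. Over the alternatives, adjusted p ranged from 4.35e-07 to 0.719 for NF-kB, 1.27e-05 to 0.782 for S100, 5.73e-09 to 0.854 for the megakaryocyte and platelet list and 2.33e-06 to 0.854 for the erythroid list.

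Cell cycle lists stood lower and the stem cell program higher in ET HSPC-like cells, and each of these rested on ET replicate 1. Kept cells of that library had a median mitochondrial share of 6.26%, against 4.19% in ET replicate 3 and 4.30% and 4.94% in H. Cluster 5, 21.9% of its HSPC-like class, had a median share of 14.4%. These lists were still called with clusters of high mitochondrial share left out. The G2/M list had a median of -0.59 over 17 genes, 0 of them positive (camera adjusted p = 0.000158; adjusted p = 0.854 with an estimated correlation) and the S phase list -0.33 over 18 genes, 1 of them positive (camera adjusted p = 0.00952; adjusted p = 0.854 with an estimated correlation). AURKA stood at -0.92, CDK1 at -0.65, UHRF1 at -0.96 and RRM2 at -0.81, with no member past either threshold. Without ET replicate 1 these 4 were -0.33, -0.12, -0.40 and -0.31, and without ET replicate 3 they were -1.89, -1.47, -1.87 and -1.57, each past the threshold over all genes; CDK1 was -0.43 without H replicate 1. Without ET replicate 1 the medians were 0.02 for G2/M and 0.29 for S phase, and without ET replicate 3 they were -1.65 and -1.38. Without H replicate 1 they were -0.35 and -0.14, the latter without a call. The stem cell program had a median of 0.44 over 15 genes, 12 of them positive (camera adjusted p = 0.0478; adjusted p = 0.854 with an estimated correlation), with MECOM at 1.17 (0.27 without ET replicate 1, and 1.72 without ET replicate 3, where it passed over all genes), HOPX at 0.52 (0.27 without H replicate 1 and 0.83 without H replicate 2) and SPINK2 at -0.37. That median was -0.03 without ET replicate 1 and 0.13 without H replicate 1, with no call in either case, and 0.72 without ET replicate 3. With each library clustered alone none of these 3 lists was called, and with doublets kept the S phase and stem cell calls ended. The S phase call also ended at Leiden resolution 2 and with the unnamed HSPC-matching cluster added. Adjusted p ranged over the alternatives from 7.29e-23 to 0.854 for S phase, 6.77e-21 to 0.854 for G2/M and 9.03e-07 to 0.854 for the stem cell program.

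Lymphoid transcripts stood lower as lists in the HSPC-like class of ET. Cluster 2, with IGLL1 among its leading genes, held 47.3% and 35.7% of that class in H replicates 1 and 2. It held 4.53% and 1.28% in ET replicates 1 and 3. The makeup of the class therefore cannot be told apart from a change within its cells. The B and plasma cell list had a median of -0.86 over 12 genes, 3 of them positive (camera adjusted p = 0.000166; adjusted p = 0.719 with an estimated correlation), and was the list that fry called as well (adjusted p = 0.0181). Its members VPREB1 at -1.72, IGLL1 at -1.44 (75.4 and 158 CPM in ET, 351 and 282 CPM in H) and JCHAIN at -1.95 did not pass over all genes or over the list alone. Its median was -0.41 without H replicate 2. The T and NK cell list had a median of -0.99 over 7 genes, 2 of them positive (camera adjusted p = 0.00217; adjusted p = 0.854 with an estimated correlation), where IL7R, the interleukin-7 receptor, fell by 2.72 when adjusted over the list alone. For the T and NK cell list in HSPC-like cells, ET against H, the median was -0.46 without ET replicate 1, where the call ended, -2.13 without ET replicate 3, -0.60 without H replicate 1 and -1.49 without H replicate 2. With doublets kept neither lymphoid list was called, at -0.35 and -0.40, nor with each library clustered alone. The B and plasma cell call also ended at Leiden resolution 2 and in the HSPC cluster filled by each library, and the T and NK cell call with the stricter cell filter. Over the alternatives IL7R ranged from -3.36 to -0.75, VPREB1 from -2.31 to -0.87 and JCHAIN from -2.45 to 0.90. Adjusted p ranged over the alternatives from 9.34e-05 to 0.719 for the B and plasma cell list and from 1.48e-06 to 0.854 for the T and NK cell list.

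Camera called 9 lists in HSPC-like cells, against 3 with doublets kept, 5 at Leiden resolution 2, 4 with each library clustered alone, 5 with the unnamed HSPC-matching cluster added and 13 with equal numbers of cells. It called 8, 13, 6 and 13 without ET replicate 1, ET replicate 3, H replicate 1 and H replicate 2. It called none of the following lists. The galectins had a median of 0.09 and a mean of -0.10 over 8 genes (adjusted p = 0.865), with LGALS3BP at -1.48 (-0.58 without H replicate 1), LGALS3 at 1.10 (0.29 without ET replicate 1) and CLC at -1.19 (-0.15 without H replicate 2). Over the alternatives LGALS3 ranged from -0.01 to 1.60 and CLC from -1.86 to 0.87. In the TGF-beta and matrix list (median 0.09), SKIL, an antagonist of SMAD signalling, rose by 2.40 when adjusted over the list alone. THBS1 passed too, at 2.63, but monocyte RNA would bring 54.8% and 81.0% of its level in ET. When adjusted over its list alone MRC1 rose by 1.91 in the list of scavenger receptors and complement (median 0.40), while IRF8 fell by 1.84 in the dendritic cell list (median 0.33, mean 0.17, camera direction down; IRF8 ranged from -2.33 to -0.62 over the alternatives). None of these passed over all genes. Medians were -0.08 for galectin-1 binding partners, -0.15 for the inflammasome, -0.02 for the type I interferon response, -0.17 for the interferon-gamma response and -0.18 for MHC class II. They were 0.21 for JAK-STAT targets, 0.01 for Toll-like receptor sensing (mean -0.05), -0.15 for migration and adhesion, -0.06 for oxidative burst and antioxidants and 0.02 for glycolysis. They were -0.02 for nuclear oxidative phosphorylation, 0.25 for mitochondrially encoded transcripts, 0.07 for ribosomal proteins, 0.20 for immediate early genes and -0.10 for heat shock. The unfolded protein list stood at -0.07, azurophil granule genes at 0.17 and neutrophil granule genes at -0.13.

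The difference of the ET effect between monocyte-like and HSPC-like cells asks whether ET and H differ more in one class than in the other. SLC16A10, which encodes a transporter of aromatic amino acids, had the smallest p: its ET effect was 5.13 (log2, SE 0.42) higher in monocyte-like cells, just short of the threshold (edgeR adjusted p = 0.0513). By edgeR 0 of 19707 genes passed, and 1007 had an unadjusted p under 0.05, close to the share expected with no change. DESeq2 called 67. For LGALS1 the difference was 1.32 (SE 0.41), with an unadjusted p of 0.0128 and an adjusted p of 0.779. It was 0.87 without ET replicate 1. With ET replicate 1, ET replicate 3, H replicate 1 or H replicate 2 left out, edgeR called 9, 21, 48 and 50 genes, and SLC16A10 passed in each of these 4 fits. With RLE size factors SLC16A10 passed as well (5.19, adjusted p = 0.032, range over its alternatives 9.11e-16 to 1.000). With doublets kept its value was 2.86.

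In ET basophil, mast cell or eosinophil progenitor-like cells, ALOX5 and ALOX5AP were among 29 genes that fell. ALOX5, an enzyme of leukotriene synthesis, fell by 3.25 (SE 0.41), with 5.41 and 6.16 CPM in ET and 41.1 and 74.8 CPM in H, and its helper protein gene ALOX5AP fell by 1.83, with 31.1 and 29.5 CPM in ET and 108 and 105 CPM in H (edgeR adjusted p = 0.0391 for both). DPP10, of the dipeptidyl peptidase family, rose by 1.92 (SE 0.25, adjusted p = 0.0391), with 433 and 739 CPM in ET and 160.0 and 153 CPM in H, and the carbonic anhydrase gene CA1, also on the erythroid marker list, rose by 3.54 (adjusted p = 0.0472). The endogenous retroviral transcript ERVMER61-1 fell by 8.25 (SE 0.49, edgeR adjusted p = 0.00205), and SLC35F3 fell by 7.19 (adjusted p = 0.0391). Over the alternatives SLC35F3 ranged from -8.95 to -4.25. C5orf17 was at 0 in both ET libraries and at 70.2 and 48.1 CPM in H (adjusted p = 0.0134). The class held 33 cells in ET replicate 1 and 134 in ET replicate 3, against 62 and 75 in H replicates 1 and 2. Of 10892 genes tested by edgeR, 1350 had an unadjusted p under 0.05, and DESeq2 called 98. In all, 2 genes rose and 29 fell by edgeR, and these 31 include a gene with donor-specific haplotypes, which is not named. Without ET replicate 1, ET replicate 3, H replicate 1 or H replicate 2, edgeR called 380, 77, 16 and 61 genes, of which 31, 27, 7 and 23 were among these 31. SLC35F3, ALOX5 and CA1 did not pass without ET replicate 3. Nor did DPP10, SLC35F3, ALOX5AP and CA1 without H replicate 1, or DPP10 and CA1 without H replicate 2. The log2 fold changes kept their direction with single libraries left out. They ranged from -3.63 to -2.77 for ALOX5, -1.84 to -1.78 for ALOX5AP and -8.68 to -6.43 for SLC35F3. For CA1 they ranged from 3.21 to 3.73 and for DPP10 from 1.47 to 2.25. With doublets kept edgeR called 6 genes, 5 of them among the 31; with the stricter cell filter 13, 10 of them; at Leiden resolution 2 it called 10, 5 of them; with each library clustered alone 24, 9 of them; and with equal numbers of cells 3, all among the 31. Adjusted p ranged over the alternatives up to 0.349 for DPP10, 0.311 for CA1, 0.193 for ALOX5, 0.187 for ALOX5AP, 0.152 for SLC35F3, 0.0533 for C5orf17 and 0.0438 for ERVMER61-1.

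In granulocyte-monocyte progenitor-like cells, ROBO1, which encodes an axon guidance receptor, fell by 3.03 (SE 0.27, edgeR adjusted p = 0.0329), with 4.13 and 3.64 CPM in ET and 35.8 and 26.9 CPM in H. SPATC1L fell by 6.64 (SE 0.58, adjusted p = 0.0329). They were among 3 genes that passed, all lower in ET, of 15666 tested; the remaining gene has donor-specific haplotypes and is not named. A count of 1137 genes had an unadjusted p under 0.05, and DESeq2 called 43. With ET replicate 1, ET replicate 3, H replicate 1 or H replicate 2 left out, edgeR called 162, 39, 26 and 28 genes. ROBO1 and SPATC1L did not pass with doublets kept, a stricter cell filter, Leiden resolution 2 or each library clustered alone (edgeR adjusted p up to 0.314 and 0.377). Over the alternatives, ROBO1 ranged from -3.21 to -1.66 and SPATC1L from -9.90 to -4.40 (log2).

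Erythroid-like, megakaryocyte-like and B-lineage-like cells gave no gene past the threshold by edgeR. The counts were 0 of 17405, 0 of 14333 and 0 of 13071 genes, with 1169, 1515 and 961 at an unadjusted p under 0.05 and 88, 80 and 24 called by DESeq2. With single libraries left out, edgeR called 14 to 75 genes in erythroid-like, 10 to 449 in megakaryocyte-like and 29 to 265 in B-lineage-like cells. The values without ET replicate 1, ET replicate 3, H replicate 1 and H replicate 2 were 75, 14, 34 and 32 for erythroid-like, 449, 96, 12 and 10 for megakaryocyte-like and 32, 265, 29 and 43 for B-lineage-like cells.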

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

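The tests here of the HSPC clusters and of RNA from monocytes were laid down before their results were seen; the band that leaves the former open was added after its value was seen.

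LGALS1 stood out because its ET effect differed between classical monocyte-like and HSPC-like cells by 1.32 (log2, SE 0.41, unadjusted p = 0.0128), a difference that fails the correction over 19707 genes (edgeR adjusted p = 0.779). LGALS1 RNA from monocytes in HSPC-like droplets is argued against: the lowest of the 4 libraries held 7.23 times the LGALS1 that the S100A9 RNA there would bring, in ET replicate 1. The different clusters making up the HSPC class cannot be told apart from a difference between ET and H, because the cluster shared by the 4 libraries is a small one of cycling cells (1.77%, 11.1%, 10.9% and 6.48% of the class in ET replicates 1 and 3 and H replicates 1 and 2). In that cluster alone the difference was 0.68 (SE 0.36, adjusted p = 0.784, range over the alternatives 0.0515 to 1.000), a value that does not carry over to HSPC-like cells in general. A biological difference between ET and H in LGALS1 stays open. Leaving out single libraries moved the value between 0.87 (without ET replicate 1) and 1.86 (without ET replicate 3). These values do not show in which class such a difference would act.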

How the results depend on the processing

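The alternatives that left out clusters of high mitochondrial share, added the unnamed HSPC-matching cluster or used the HSPC cluster filled by each library were chosen after the data were seen. Each fit without a library leaves 1 library in a group, which is assumed to vary like the libraries of the other group. No paired analysis was possible because the ET and H libraries share a single replicate number and no label links them. Of the tested values, 1438 kept their direction and side of the threshold, 119 newly passed, 105 no longer passed and 32 changed sign. The cause was not tested for any value below, except that fewer libraries or other numbers of genes tested follow from how an alternative is built.

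RLE size factors gave 1 gene for the difference of the ET effect between the classes (0 as reported). No filter on low counts gave 65 genes in monocyte-like, 197 in B-lineage-like, 412 in basophil, mast cell or eosinophil progenitor-like (BMEP-like), 394 in erythroid-like, 288 in granulocyte-monocyte progenitor-like and 396 in megakaryocyte-like cells, and 135 for the difference. DESeq2 gave 158 in monocyte-like, 186 in HSPC-like, 24 in B-lineage-like, 98 in BMEP-like, 88 in erythroid-like, 43 in granulocyte-monocyte progenitor-like and 80 in megakaryocyte-like cells, 67 for the difference, and LGALS1 at -0.00579 in BMEP-like cells. An estimated correlation gave 0 lists in monocyte-like and 0 in HSPC-like cells. It also missed a simulated 2-fold shift of 38 genes, drawn independently, in both (camera adjusted p = 0.133 and 0.153).

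With doublets kept there were 12 lists in monocyte-like and 3 in HSPC-like cells, 6 genes in BMEP-like and 7 in megakaryocyte-like cells, and LGALS1 stood at -0.0493 in granulocyte-monocyte progenitors. The share differences (ET minus H, percentage points) were -2.61 for B-lineage-like and -3.03 for plasmacytoid dendritic cell-like cells. The stricter cell filter gave 1 gene in B-lineage-like, 13 in BMEP-like, 1 in granulocyte-monocyte progenitor-like and 4 in megakaryocyte-like cells, and 1 for the difference. Under it CLC in HSPC-like cells was 0.18, LGALS1 in BMEP-like cells -0.18, and the share differences -2.21 for B-lineage-like and -3.29 for unnamed cells.

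Leiden resolution 2 gave 11 lists in monocyte-like and 5 in HSPC-like cells, 10 genes in BMEP-like, 3 in megakaryocyte-like cells and 1 for the difference. LGALS1 was 0.23 in B-lineage-like and -0.0350 in granulocyte-monocyte progenitor-like cells, and the B-lineage-like share difference -2.59. With each library clustered on its own there were 2 genes and 14 lists in monocyte-like and 4 lists in HSPC-like cells. There the stem cell program in monocyte-like cells was -0.0801, CLC 0.87 and GP1BB -0.0147 in HSPC-like cells, and LGALS1 -0.37 in BMEP-like and -4.14 in B-lineage-like cells (-0.17 as reported). The share differences were -5.74 for B-lineage-like, -0.965 for T or NK cell-like, 3.15 for granulocyte-monocyte progenitor-like and -1.96 for plasmacytoid dendritic cell-like cells. That clustering gave no value for megakaryocyte-like cells. Equal numbers of cells gave 2 genes in B-lineage-like, 3 in BMEP-like and 10 in megakaryocyte-like cells, with the galectin list at -0.33 in HSPC-like cells and LGALS1 at -0.20 in BMEP-like and -1.26 in erythroid-like cells (-0.41 as reported).

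The added unnamed cluster gave 5 lists in HSPC-like cells, with HBD at -0.19. The shared HSPC cluster gave 1 gene and 14 lists in HSPC-like cells and 1 gene for the difference. That cluster is one of cycling cells (TOP2A and MKI67 among its leading genes) and holds 1.77%, 11.1%, 10.9% and 6.48% of the class in ET replicates 1 and 3 and H replicates 1 and 2, so its cell cycle values say nothing on the class. There NRXN3 was -1.07, LGALS3 -0.00621, CLSPN 0.0105, JCHAIN 0.90, the galectin list -0.12 and the S phase list 0.18.

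Leaving out each library in turn gave 2 to 80 genes in monocyte-like, 0 to 801 in HSPC-like, 29 to 265 in B-lineage-like, 16 to 380 in BMEP-like, 14 to 75 in erythroid-like, 26 to 162 in granulocyte-monocyte progenitor-like and 10 to 449 in megakaryocyte-like cells. It gave 9 to 50 genes for the difference and 8 to 12 lists in monocyte-like cells. LGALS1 ranged from -0.17 to 0.97 in monocyte-like, -2.02 to 0.12 in HSPC-like, -0.72 to 0.41 in BMEP-like and -0.39 to 0.32 in granulocyte-monocyte progenitor-like cells. The immediate early list in monocyte-like cells ranged from -0.19 to 0.60. In HSPC-like cells the galectin list ranged from -0.37 to 0.14, S phase from -1.38 to 0.29, G2/M from -1.65 to 0.0160, the stem cell program from -0.0300 to 0.72 and CLSPN from -1.65 to 0.0407.

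OLR1 in classical monocyte-like cells passed under each alternative run (adjusted p 2.59e-27 to 0.0475), as did ERVMER61-1 in BMEP-like cells (highest adjusted p 0.0438). The number of cells limits the smaller classes: plasmacytoid dendritic cell-like and T or NK cell-like cells had 13 and 16 cells in ET replicate 3, under the minimum of 20. Among the tested classes, BMEP-like cells numbered 33 and megakaryocyte-like cells 46 in ET replicate 1. ET replicate 1 was the shallowest library per cell (median 9886 UMIs, against 25390 in ET replicate 3), and no alternative equalised the depth per cell.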

Other observations

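The tests of handling stress, of a gained region and of a chance run of neighbours, with its control, were chosen only after the results were seen; the other tests in this part were laid down before.

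TNNT1, TNNI3, DNAAF3 and SYT5, which encode slow skeletal troponin T, cardiac troponin I, an assembly factor of ciliary dynein and a synaptotagmin, lie close together, with 1 other tested gene among them, on the minus strand of chromosome 19, from 55132794 to 55180441. In HSPC-like cells TNNT1 held 5.22 and 6.75 CPM in ET and 0.172 and 0.0861 CPM in H, and DNAAF3 held 4.73 and 4.63 CPM in ET and 0.344 and 0.224 CPM in H. TNNI3 had 204 UMIs over the ET libraries and 0 over the H libraries, at least 27.8-fold higher against a floor of 3 counts in each H library. Of 17 values of these genes tested over 6 classes, 17 had both ET libraries above both H libraries, 16 had an unadjusted p under 0.05 and 0 passed by edgeR. Over all genes tested, the groups did not overlap, in either direction, for 34.3% (HSPC-like) to 43.5% (megakaryocyte-like) in these classes. The genes were picked as high in ET HSPC-like cells, and the classes come from the same 4 libraries, so the count is no independent support.

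A shared change of this stretch may lie behind the run, as a hypothesis found and tested on the same data. A gain of the surrounding region is argued against: the other 62 tested genes within 1 Mb had a median log2 fold change of 0.0164 (quartiles -0.19 and 0.28). A chance run of neighbours cannot be told apart. Windows of 5 neighbouring genes with at least 4 above a log2 fold change of 2 were counted. The real order held 3, all overlapping on this stretch, where the other tested gene among the named ones also stood at 3.35. In 0% of 1000 shuffled gene orders were there as many. The 2 windows lower in ET were not part of that comparison. Another split of the 4 libraries gave up to 4 windows in a direction. A biological difference between ET and H was not tested further.

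The higher NF-kB and TNF response of ET classical monocyte-like cells may reflect inflammatory signalling, as a hypothesis found and tested on the same data. Handling stress cannot be told apart: the heat shock list had a median of -0.41, while the immediate early genes, another sign of handling, were called higher (0.23, camera adjusted p = 0.0261; adjusted p = 0.813 with an estimated correlation), though not without ET replicate 3 (-0.19) or H replicate 2 (-0.11). Damaged cells are argued against as the whole cause: without clusters of high mitochondrial share the list median was 1.31, above the line of 0.66 set for that explanation. RNA from progenitor cells in the droplets is argued against, as the list's genes stood 3.10 (log2, median) higher in monocyte-like than in HSPC-like cells of ET replicate 1 and 5.51 in ET replicate 3. A difference in processing between single libraries stays open, since the median was 0.12 without ET replicate 3, and another split of the 4 libraries gave a median size of 1.23.

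The 4 libraries can be split into pairs in 3 ways, too few for a share under 0.05. In classical monocyte-like cells 1 of the 3 splits, the real one, gave as many genes as the real 4, and the highest other gave 0 by edgeR. In HSPC-like cells the real split gave 0 and so did the others, so 3 of the 3 splits gave as many; the counts at an unadjusted p under 0.05 were 1031 for the real split and 321 and 1466 for the others.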
